A study of Caenorhabditis elegans with 32 samples.

How the data were processed

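Whole worms of Caenorhabditis elegans, wild type (WT) and hrde-1 mutants, were sampled in the generations P0, F1, F2 and F3 under the labels normoxia and hypoxia, with 2 libraries for each of 16 groups. Per the labels' protocols, worms had been kept at 20 °C with food over several generations, RNA was taken with a mirVana kit, poly(A) RNA was bound to beads, and libraries of a NEXTflex qRNA-Seq kit were read from both ends on a HiSeq4000. The labels do not say whether the molecular tags of that kit were used in counting. The submitters' processing notes name cutadapt 2.5, Bowtie2, featureCounts, RSEM and edgeR. Their roles and the genome build are not given in the sources used here.

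The deposited table holds estimated counts per gene that the authors did not normalize, in 32 columns and 46904 genes. In 30 of the columns at least 97.8% of values were whole numbers. The 2 F2 WT normoxia columns were each found to be a mean of 3 values, of which the F1 and F3 WT normoxia columns of the same replicate number are 2. Column names gave each column its sample, and no column was left without one. Totals per library ran from 9722580 to 16555982 estimated counts. Gene names came from the table, and 44017 of its IDs (93.8%) matched the WBcel235 annotation of Ensembl, where 1754 carry another symbol. That annotation gave all coordinates, as 1-based positions. Reads from near-identical gene copies, such as major sperm protein, histone and vitellogenin genes, cannot be assigned with certainty, and values of such genes are uncertain.

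Tests had been planned for raw counts, so the estimated counts were rounded to whole numbers. CPM, counts scaled to a common library size, used effective library sizes from edgeR's TMM factors. Genes passed edgeR's filterByExpr, and tests were edgeR 4.0.16 quasi-likelihood tests (glmQLFit and glmQLFTest) in R 4.3.3 with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Single generations, differences between strains and differences between P0 and later generations came from 1 fit of all 32 libraries with a mean for each group, so that the groups share an estimate of the spread. Results pooled over generations came from additive models of the libraries concerned with generation as a term. Errors of log2 fold changes are standard errors, computed as the size of the fold change over the square root of F. Values in groups are means with SDs.

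The remainder of the F2 WT normoxia columns was computed as 3 times the column minus the F1 and F3 WT normoxia columns of the same replicate number. Results with it come from the same models with the remainder in place of the columns. That the remainder is the F2 WT normoxia library is an inference from the values.

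Before the data were examined, 30 gene lists were fixed: HIF-1 pathway, glycolysis and gluconeogenesis, oxidative phosphorylation, mitochondrially encoded genes, heat shock, mitochondrial and endoplasmic reticulum (ER) unfolded protein response, oxidative stress and metals, hydrogen sulfide and cysteine, lipid metabolism, vitellogenins, oocyte and eggshell, early embryonic, sperm, major sperm proteins, cuticle and molting, collagens, cell cycle, meiosis and germline, small RNA pathways, reported nuclear RNAi targets, histones, ribosomal proteins, innate immunity, intracellular pathogen response, neuropeptides, neuronal, muscle and intestine markers, insulin and DAF-16, and autophagy. Of their entries 5 matched no gene of the table. Lists with at least 4 tested members were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry without standardization, since its standardized p changed with the order of the libraries. P-values of lists were adjusted over all lists and comparisons. Counts adjusted over the list alone apply the adjustment to the list's members only.

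The genes named were chosen by a rule fixed with the lists. It takes hrde-1 and hif-1 everywhere. For each count it takes called genes whose groups do not overlap in CPM, or for pooled results have the same sign in each generation, with at least 1 CPM in the higher group. Of these it takes the 8 largest changes in each direction with a gene-class symbol and the 2 largest of any name. For each list it takes up to 4 called members per direction with the smallest p, or up to 2 members as values where fewer than 2 are called. Not every gene the rule gives is printed. Where a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with a 95% counting interval.

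Alternatives fixed at that time were DESeq2's size factors in the edgeR fit, DESeq2 1.42.0 itself with its Wald test (its likelihood ratio test for tests of several contrasts at once), no filter, a filter of 5 CPM in 2 libraries, the replicate number as a block, fits of the groups compared alone, averages of contrasts for pooled results, each generation left out of pooled results, shared calls with an absolute log2 fold change of at least 1, and each library left out in turn. A library left alone in its group is then assumed to vary like the other groups. The alternatives added after seeing the data were the remainder, the remainder with the block, DESeq2 with the remainder, all libraries but the F2 WT normoxia columns, and library sizes without 27 vitellogenin and ribosomal RNA genes. In all 48 alternatives were fitted.

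The tests were tested on simulated data with 200 changed genes, drawn from the means, library sizes and spreads of the libraries. The changed genes had a mean of at least 5 CPM in WT normoxia of F1 to F3 and changed alike in each of these generations. Every library was drawn on its own. False calls from the F1 and F3 libraries within the deposited F2 WT normoxia columns were therefore not simulated. For the WT F1 comparison, over 15354 genes, 9.0% of changes of 1.5-fold, 40.3% of 2-fold and 87.9% of 4-fold changes were recovered, with 5 unchanged genes called. For WT pooled over F1 to F3, over 14327 genes, the shares were 46.3%, 85.1% and 95.5%, with 9 unchanged genes called.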

Results

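Poly(A)-selected RNA from whole worms of Caenorhabditis elegans was measured in 32 libraries, which form 16 groups of 2. The groups combine wild type (WT) and hrde-1 mutant worms, the generations P0, F1, F2 and F3, and the labels normoxia and hypoxia. HRDE-1 is an Argonaute protein of the germline nucleus that acts in inherited RNA interference. Per the labels, L4 larvae spent 16 h at 0.1% oxygen and 20 °C and then went back to ambient oxygen of about 20%. The labels do not say whether worms of F1 to F3 were exposed themselves, so hypoxia in those generations names the group and nothing more. The series asks how the transcriptome changes from P0 to F3 after hypoxic stress in each strain. Library totals ran from 9722580 to 16555982 estimated counts. Outside the F2 WT normoxia group, described below, replicates correlated across genes with Pearson's r between 0.903 and 0.994. No label says that replicates came from separate cultures, so p-values measure only the spread between these samples. Generation goes together with whatever else differed between the harvests, since no label gives a date or batch.

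Both F2 WT normoxia columns hold other libraries. Multiplied by 3, each stayed, within 0.05, at or above the sum of the F1 and F3 WT normoxia columns of the same replicate number in all 46904 genes, and 69.98% and 71.1% of its values above 0 were not whole numbers. With other pairings of replicate numbers it fell below the sum in at least 1434 genes. Removing the F1 and F3 columns of the same replicate number left 12555703 and 11633862 estimated counts, with 98.3% and 98.2% of values whole up to rounding. That share says little about the pairing, as it was 97.2% to 97.6% for the other pairings. This remainder is taken here as the F2 WT normoxia library by inference, since nothing deposited says so. For F2 WT and for results pooled over generations the counts of calls are given with both versions. Other values are those of the deposited columns unless the remainder is named. Results pooled over generations as deposited thus use F1 and F3 WT normoxia reads more than once. Their SDs, SEs and p-values do not rest on independent libraries.

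The hrde-1 transcript itself was present in every group, mutants included, so its level does not check the strain label. In WT normoxia hrde-1 stood at 265 ± 64.4 CPM in P0, 477 ± 53.5 in F1 and 539 ± 66.8 in F3 (mean ± SD, n = 2). In F2 it was 579 ± 19.1 in the deposited columns and 743 in the remainder. In WT hypoxia it was 860 ± 7.94 in P0, 688 ± 1.89 in F1, 749 ± 62.3 in F2 and 704 ± 22.9 in F3. In the mutant hrde-1 stood at 425 ± 113, 608 ± 8.17, 459.5 ± 43.4 and 449 ± 81.3 CPM in normoxia and at 561 ± 6.26, 531 ± 50.2, 477 ± 33.3 and 475 ± 75 in hypoxia, from P0 to F3. The hrde-1 gene lies on chromosome III at 4172337 to 4176159 in the WBcel235 annotation.

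The first comparison set untreated mutants against untreated WT worms, over all 4 generations. Genes that nuclear RNA interference is reported to silence were high in the mutant in each generation. C38D9.2 (chromosome V, 17567150 to 17571742) stood at 267 ± 56.8 CPM in hrde-1 worms and 1.45 ± 0.642 in WT (n = 8 columns each, those of F2 WT holding F1 and F3 libraries again), a log2 fold change of 7.59 ± 0.29 (SE) with an adjusted p of 9.74e-11 in edgeR's quasi-likelihood test. F15D4.5 (chromosome II, 13245376 to 13247774) rose by 6.58 ± 0.19, and the near-identical copies F07B7.2 and W09B7.2, which share reads, both showed 7.33 ± 0.21. With the remainder C38D9.2 stood at 7.35 and F15D4.5 at 6.46. Taken one generation at a time, the log2 fold change of C38D9.2 was 7.29 in P0, 9.25 in F1, 7.11 in F2 (6.3 with the remainder) and 7.08 in F3. Of the 8 tested genes of that list 5 rose in the pooled fit, with 5 adjusted over the list alone and a median log2 fold change of 5.11. The list's camera call held with an estimated correlation in the pooled fit and in each generation, with adjusted p = 0.0442 pooled, 0.0128 in P0, 0.0176 in F1, 0.00122 in F2 and 0.00275 in F3. With DESeq2's size factors the pooled call was lost (0.0522), and with the remainder it was kept (0.0155). The list of mitochondrial and ER stress genes was the other one to keep a call with an estimated correlation, in untreated F3 mutants and in F2 WT worms, with the values given for those comparisons, and both of these calls were lost with DESeq2's size factors (0.0522 and 0.0785). Of the 7 calls of these lists 5 were lost with the replicate number as a block.

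Other genes rose with them. F07B7.1 rose by 9.06 ± 0.21 (adjusted p 5.77e-13). The ribonuclease H gene rnh-1.3 reached 155 ± 45.1 CPM against 4.965 ± 1.29, a log2 fold change of 5.03 ± 0.15. The mitochondrial import gene timm-17B.2 rose by 4.89 ± 0.17, the fatty acid amide hydrolase gene faah-5 by 4.83 ± 0.27 and the F-box gene fbxb-14 by 6.56 ± 0.51. Y43F4A.3 had 2 counts over the WT libraries and was 842 times as high in the mutant (95% counting interval 233 to 6958). Several genes that were far lower lie side by side. Cytochrome P450 gene cyp-34A4 had no counts in the mutant and was at least 545-fold lower than in WT, the neuropeptide-like gene nlp-31 at least 282-fold and phat-3 at least 235.5-fold. All 3 are among 21 neighbouring WT-expressed genes of chromosome V, between 3889161 and 4062184, whose mutant libraries held almost no counts. Floors are 3 counts over a group, and floors and intervals cover counting error only.

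**Figure D1:**
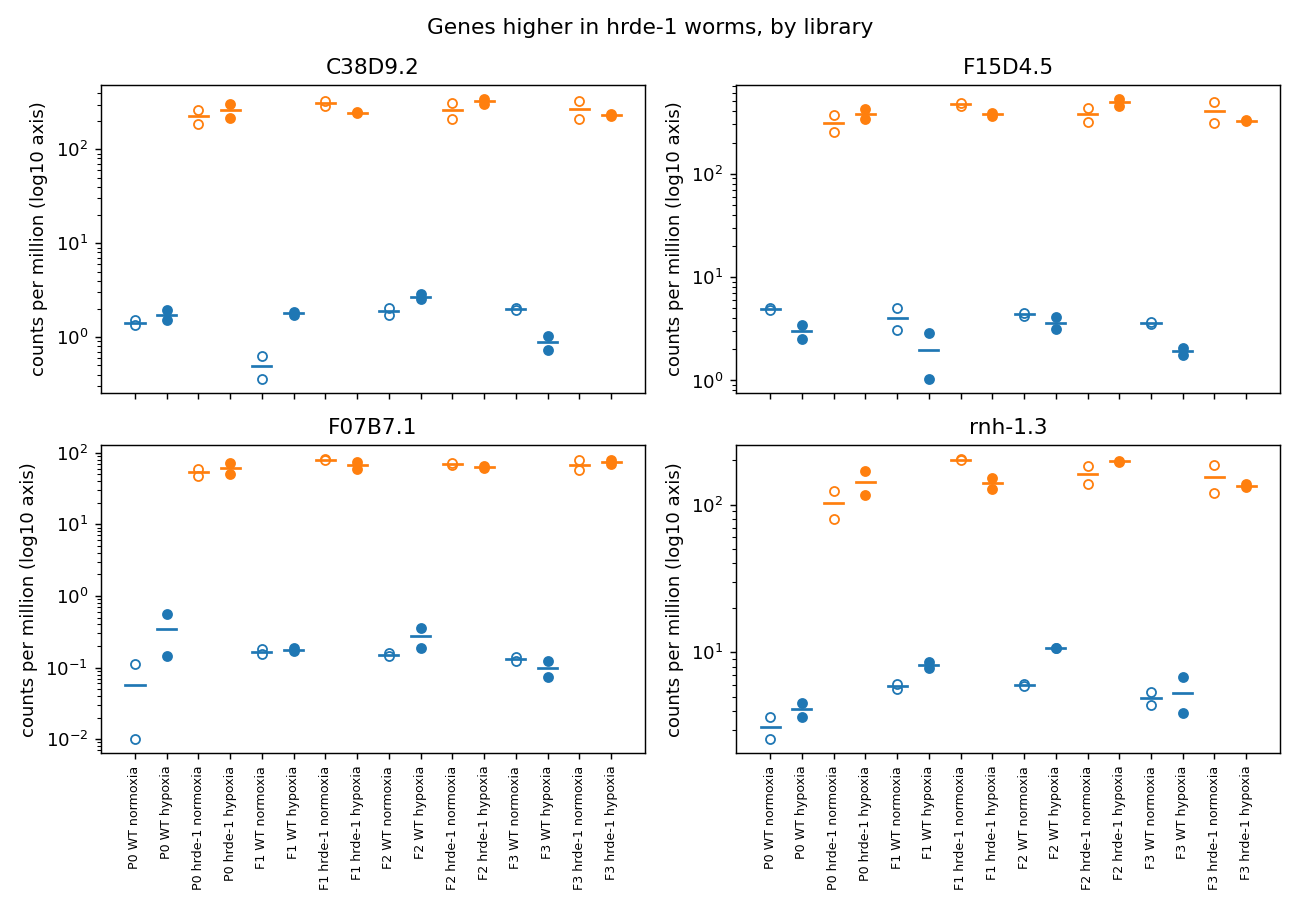
CPM of C38D9.2, F15D4.5, F07B7.1 and rnh-1.3 in each library (points, n = 2 per group) on a log10 axis, with the mean of each group as a bar, for WT (blue) and hrde-1 (orange) in normoxia (open) and hypoxia (filled). Points at 0 are drawn at 0.01. The means of C38D9.2 in untreated worms are 267 CPM in hrde-1 and 1.45 CPM in WT.

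**Figure D2:**
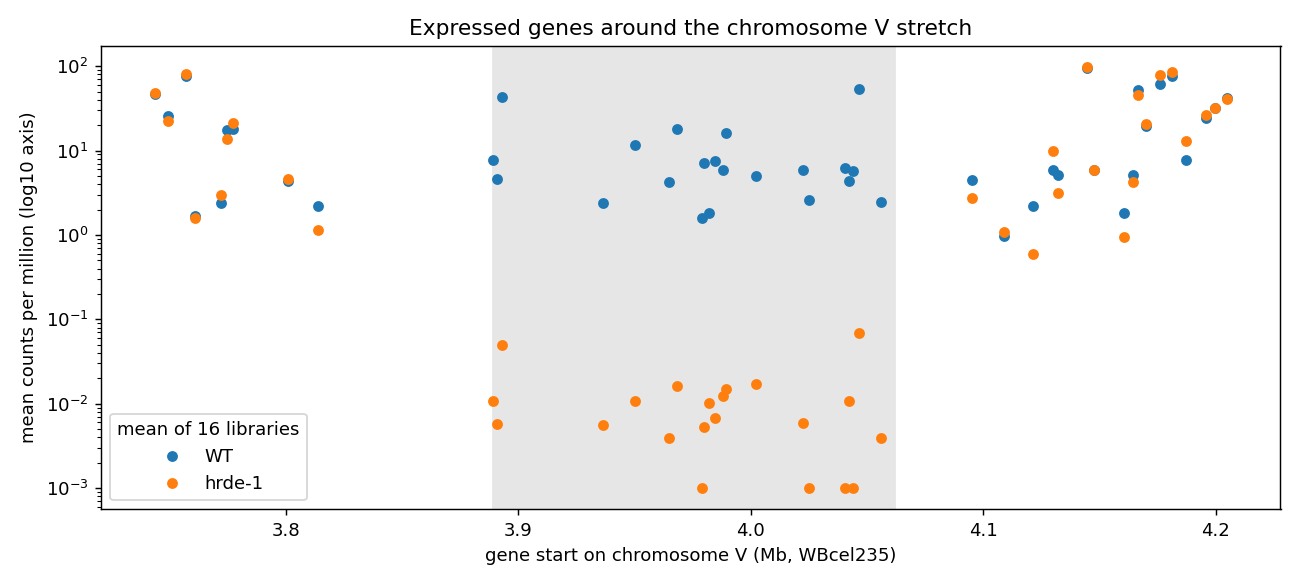
Mean CPM over the 16 libraries of each strain, on a log10 axis, for genes of chromosome V around the stretch from 3889161 to 4062184 (shaded), by start position in WBcel235. Points under 0.001 CPM are drawn at 0.001. Inside the stretch 21 genes with at least 1 CPM in WT fall under 0.1 CPM in hrde-1 worms.

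Beyond these genes, 2701 rose and 2514 fell of 15325 tested in the pooled comparison, and 2246 were called with the remainder. Neuropeptide genes were mostly lower, with 54 of 95 fallen and 1 risen (60 and 2 adjusted over the list alone; adjusted p = 0.634 with an estimated correlation). With the remainder 18 neuropeptide genes fell. Of these genes 6 lie in the chromosome V stretch, and without them 48 of 89 fell, or 12 with the remainder. Small RNA pathway genes were mostly higher, 27 of 45 risen and 1 fallen (31 and 1 adjusted over the list alone; adjusted p = 0.666 with an estimated correlation; 11 risen with the remainder). By generation edgeR called 26 of these genes higher in P0 and 21 in F1, 1 lower, but 2 higher in F2 and 1 in F3 (30, 26 with 1 lower, 2 and 1 adjusted over the list alone; lowest adjusted p 0.634 with an estimated correlation), with medians of 0.51, 0.39, 0.06 and 0.19. In F2 with the remainder the median was -0.14. Without P0, where the WT normoxia libraries stand apart, 20 small RNA pathway genes rose in the pooled fit, and without F1 9. Without F1 18 neuropeptide genes fell. Among the small RNA pathway genes the RNAi gene rde-11 rose by 0.94 ± 0.12 (adjusted p 5.69e-05), the double-stranded RNA channel gene sid-1 by 0.79 ± 0.12 and the Argonaute gene ppw-2 by 0.93 ± 0.17. Of 16 genes of the mitochondrial and endoplasmic reticulum (ER) stress response 11 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.634 with an estimated correlation; 3 risen and 1 fallen with the remainder). Without F1 7 of them rose and without F3 7 rose and 1 fell. They include the chaperone genes hsp-4, which rose by 1.55 ± 0.29, and hsp-60, by 0.98 ± 0.14. Of the HIF-1 pathway list 9 of 17 fell (9 fallen and 1 risen adjusted over the list alone; 3 fallen with the remainder, 4 without F1), and camera gave it no call (adjusted p 0.053). The hif-1 transcript, for the transcription factor of the hypoxia response, fell by 0.33 ± 0.11 (adjusted p 0.0325) and showed -0.16 with the remainder (adjusted p 0.46). The log2 fold change of hrde-1 was 0.17 (adjusted p 0.425).

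In the fit of all libraries the single generations gave 3841 calls in P0, 5687 in F1, 941 in F2 (701 with the remainder) and 1557 in F3. In P0, F2 and F3 these counts were far higher than in fits of the compared groups alone, which are given with the processing. Without the second WT library the P0 count was 1291 and without the first mutant library 1437. The F1 count was 2682, 2951 and 3025 without the first WT, first mutant and second mutant library. In F2 it was 402 and 349 without the first and second WT columns, and in F3 588 without the second WT and 3554 without the second mutant library. Major sperm protein genes, which share reads among near-identical copies, were higher in P0 mutants (27 of 30 risen, 29 adjusted over the list alone, median 3.12) and lower in F1 mutants (25 fallen, 28 adjusted over the list alone, median -1.68). Both calls were lost with an estimated correlation (adjusted p = 0.634 and 0.677). Of 30 cuticle and molting genes 1 rose and 0 fell in P0 mutants by edgeR, also adjusted over the list alone, with a median of -0.72 and no camera call (adjusted p 0.172). No test compared these lists between P0 and F1. Of 124 collagens 53 fell and 7 rose in F1 (63 and 7 adjusted over the list alone, median -2.62, or -2.48 at the count floor; adjusted p = 0.866 with an estimated correlation), and 26 of 30 cuticle and molting genes fell with 1 risen (29 and 1 adjusted over the list alone; adjusted p = 0.666 with an estimated correlation). Muscle markers fell in 12 of 23 cases in F1 (also adjusted over the list alone, median -0.73; adjusted p = 0.787 with an estimated correlation) and neuropeptide genes in 69 of 95 with 1 risen (70 and 2; adjusted p = 0.634), or 63 of 89 without those of the stretch. Collagens, cuticle genes, major sperm proteins and muscle markers also set apart the 2 untreated F3 hrde-1 libraries, by medians (second minus first, log2) of 3.76, 3.92, 1.27 and 0.77, so these F1 differences are not shown to come from the genotype. Of 78 ribosomal protein genes 46 fell in F1 (49 adjusted over the list alone, median -0.37; adjusted p = 0.727 with an estimated correlation). In P0, 5 of 12 mitochondrially encoded genes fell and 2 rose (6 and 2 adjusted over the list alone; adjusted p = 0.699 with an estimated correlation, and camera made no call). In F3 the list of mitochondrial and ER stress genes rose in 10 of 16 members (11 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.022). The hrde-1 transcript was higher in P0 mutants by 0.68 ± 0.17 (adjusted p 0.00759) and hif-1 lower in F1 mutants by -0.8 ± 0.15 (adjusted p 0.00072). In F2 the hrde-1 log2 fold change was -0.33 (adjusted p 0.318), or -0.7 with the remainder (adjusted p 0.0263). The genotype effect differed among generations for 1516 genes (3701 with the remainder). Untreated worms differed among generations for 5682 genes in WT (8651 with the remainder) and 4406 in hrde-1.

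The next comparison asked what hypoxia changed in the exposed generation of WT worms. Most listed yolk, eggshell and germline transcripts were higher and most neuronal transcripts lower, but no call of these lists held with an estimated correlation. The 2 P0 WT normoxia libraries stood apart, with the highest TMM factors of the 32 (1.361 and 1.392) and a mean r of 0.83 and 0.808 with 22 libraries of later generations, against 0.929 and 0.932 for P0 WT hypoxia. Untreated P0 mutants differed from them the same way, with 21 of 23 oocyte and eggshell genes (21 adjusted over the list alone) and 18 of 27 meiosis and germline genes (19) higher and 17 of 95 neuropeptide genes (16) lower, or 11 of 89 without those of the chromosome V stretch. With an estimated correlation those 3 calls were lost too (adjusted p = 0.634). The yolk protein gene vit-1 (chromosome X, 7727889 to 7733168) went from 70 ± 21.3 to 6583 ± 410 CPM (n = 2 each), a log2 fold change of 6.56 ± 0.57 with an adjusted p of 4.3e-07. The vitellogenin genes together changed far less, from 6.235 ± 0.544% of the counts in normoxia to 11.415 ± 0.318% in hypoxia. The ATPase gene catp-2 had no counts in normoxia and 48.4 ± 20 CPM in hypoxia, at least 566-fold higher, and the sodium/proton exchanger gene nhx-6 rose by 7.05 ± 0.85. The metallothionein gene mtl-1 fell from 176 ± 39.8 to 1.07 ± 0.732 CPM (-7.32 ± 0.82, adjusted p 4.09e-06), and maph-9, for a microtubule-associated protein, was at least 38.1-fold lower. The hrde-1 transcript rose by 1.7 ± 0.18 (adjusted p 2.16e-06), while hif-1 showed -0.27 (adjusted p 0.155). In all 3075 genes rose and 3747 fell of 15537 tested. The count was 3717 without the second P0 WT normoxia library and 4224 and 4517 without the first and second P0 WT hypoxia libraries.

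Every one of 23 oocyte and eggshell genes rose, also when adjusted over the list alone, with a median of 1.34. Examples are cpg-1 (2.1 ± 0.26, adjusted p 1.1e-05) and cbd-1 (1.97 ± 0.27), for proteins of the eggshell, and mex-5 (1.89 ± 0.25), which sets embryonic polarity. All 6 vitellogenin genes rose, 27 of 30 major sperm proteins rose (msp-76, 2.44 ± 0.45) and 12 of 25 other sperm genes did, among them the spermatogenesis Argonaute gene alg-3 (4.75 ± 0.69). Those counts were unchanged when adjusted over the list alone. Of 27 meiosis and germline genes 20 rose (22 adjusted over the list alone), with the P-granule gene pgl-1 at 1.43 ± 0.17, and of 28 cell cycle genes 21 rose (23), with the replicative helicase gene mcm-2 at 1.53 ± 0.2. Of 45 small RNA pathway genes 32 rose (33 adjusted over the list alone), led by the germline Argonaute gene wago-4 at 1.56 ± 0.16. Glycolysis and gluconeogenesis genes rose in 13 of 23 cases and fell in 2 (15 and 2 adjusted over the list alone). Neuropeptide genes fell in 61 of 95 cases (67 adjusted over the list alone, median -1.19) and neuronal markers in 17 of 21 (17), with the synaptic vesicle gene rab-3 at -2.16 ± 0.3. Camera called all 10 of these lists, and all 10 calls were lost with an estimated correlation (adjusted p from 0.634 to 0.669).

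The other lists moved both ways in P0, and camera made no call for any of them (lowest adjusted p 0.0514). HIF-1 pathway genes rose in 2 and fell in 4 of 17 cases (2 and 2 adjusted over the list alone), and mitochondrial and ER stress genes rose in 5, hsp-4 by 1.94 ± 0.42, and fell in 3 of 16. Oxidative phosphorylation genes rose in 9 and fell in 1 of 36 cases (6 and 1 adjusted over the list alone), collagens in 31 and 8 of 124 (30 and 8), ribosomal protein genes in 13 and 3 of 78 (7 and 2) and intestinal markers in 6 and 4 of 19. The collagen gene col-101 rose by 4.04 ± 0.45 and the acyl-CoA dehydrogenase gene acdh-1 by 3.63 ± 0.39. Cuticle and molting genes rose in 4 and fell in 12 of 30 cases (4 and 13 adjusted over the list alone), among the fallen the nuclear receptor gene nhr-25 (-2.91 ± 0.44) and the fibrillin gene fbn-1 (-2.76 ± 0.5). Heat shock genes rose in 3 and fell in 9 of 19 cases, oxidative stress and metal genes in 2 and 11 of 27, innate immune genes in 4 and 12 of 35, and early embryonic genes in 1 and 6 of 16. Muscle markers rose in 2 and fell in 8 of 23 cases, insulin and DAF-16 genes in 3 and 8 of 28, autophagy genes in 6 and 9 of 30, hydrogen sulfide genes in 3 and 4 of 13 and intracellular pathogen response genes in 1 and 3 of 18 (1 and 2 adjusted over the list alone). Lipid genes rose in 6 and fell in 9 of 39 cases (6 and 8 adjusted over the list alone), a balance that DESeq2 turned to 11 and 10, and the desaturase gene fat-7 fell (-3.78 ± 0.43). Histone genes rose in 4 and fell in 8 of 49 cases (3 and 6 adjusted over the list alone) and the reported nuclear RNAi targets in 2 and 2 of 8. For the other lists the counts were the same adjusted over the list alone. The 12 mitochondrially encoded genes had no call in either direction, with a median of -0.21.

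**Figure D3:**
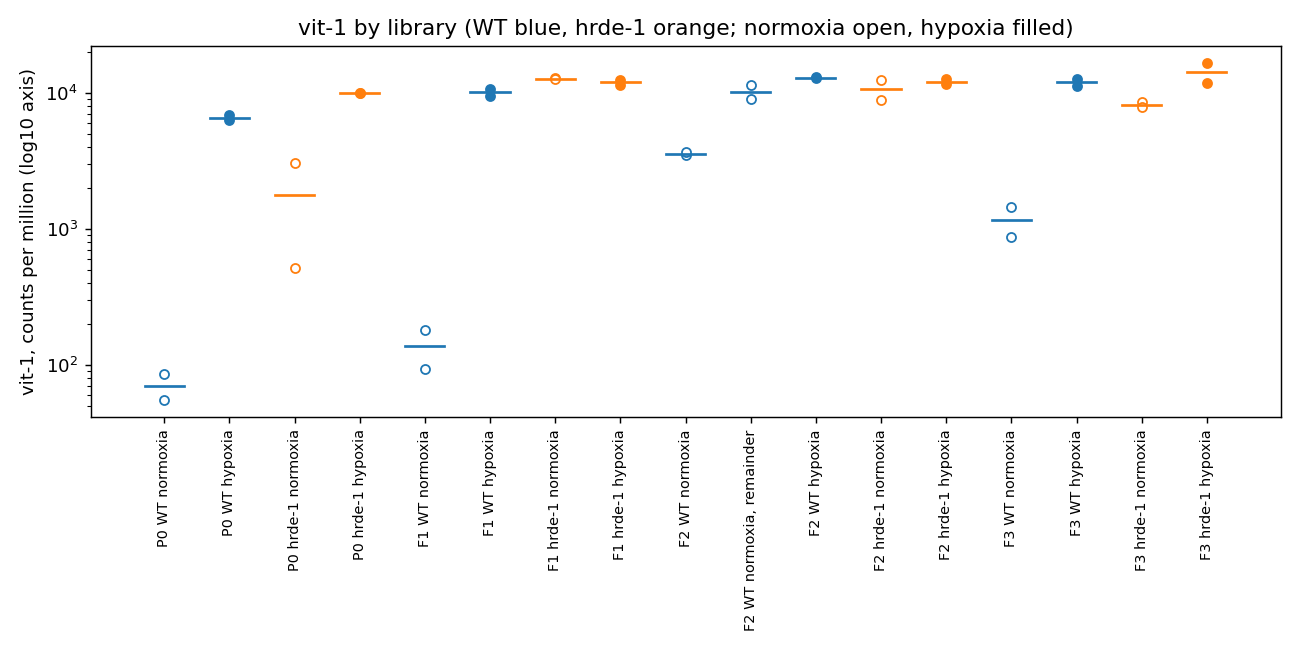
CPM of vit-1 in each library (points) on a log10 axis, with the mean of each group as a bar, for WT and hrde-1 worms in normoxia (open) and hypoxia (filled) from P0 to F3. The F2 WT normoxia group is shown as deposited (mean 3589 CPM) and as the remainder (10200 CPM). WT normoxia means are 70 CPM in P0, 136 in F1 and 1158 in F3.

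In F1, WT worms of the hypoxia group again had more vit-1, at 10180 ± 898 CPM against 136 ± 61.1 (6.22 ± 0.57, adjusted p 3.12e-07). The vitellogenin genes together held 11.55 ± 0.537% of the counts against 8.525 ± 1.704% in normoxia. The folate transporter family gene folt-2 rose by 6.71 ± 0.59, and drd-50 was at least 79.2-fold higher than in normoxia, where it had no counts. Lower were the C-type lectin gene clec-70, by 227 times with 1 count in hypoxia (95% counting interval 40.4 to 9007), and F07C4.12, at least 82.3-fold. The glyoxylate cycle gene icl-1 fell by 3.21 ± 0.27 (adjusted p 1.39e-07), as did the gluconeogenesis gene pck-2 (-1.76 ± 0.16) and the desaturase gene fat-3 (-3.29 ± 0.31). The hif-1 transcript fell by 0.84 ± 0.15 (adjusted p 0.000787) and hrde-1 rose by 0.53 ± 0.17 (adjusted p 0.0446). In all 900 genes rose and 1450 fell, a split of 38.3% higher that became 49.9% without vitellogenin and ribosomal RNA genes in the library size. The count was 873 without the first F1 WT normoxia library, 1337 and 961 without the first and second F1 WT hypoxia libraries, and 3796 in a fit of the 4 libraries alone.

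Of 16 mitochondrial and ER stress genes 10 rose (11 risen and 1 fallen adjusted over the list alone; adjusted p = 0.0565 with an estimated correlation), among them the disulfide isomerase gene pdi-6 (1.69 ± 0.16) and the co-chaperone gene dnj-7 (1.38 ± 0.15). Neuropeptide genes fell in 41 and rose in 1 of 95 cases (54 and 2 adjusted over the list alone, median -1.14; adjusted p = 0.634 with an estimated correlation), with flp-9 at -2.1 ± 0.33. The neurosecretory genes ida-1 (-1.56 ± 0.21) and egl-3 (-1.44 ± 0.21) fell. Innate immune genes rose in 12 and fell in 4 of 35 cases (14 and 7 adjusted over the list alone; adjusted p = 0.634 with an estimated correlation). The lysozyme gene lys-2 rose by 4.84 ± 0.53, the saposin-like gene spp-8 fell by 2.29 ± 0.28, and T24B8.5, a gene of the immune response, was 106 times as high with 3 counts in normoxia (95% counting interval 35.8 to 515). Lipid genes fell in 17 and rose in 6 of 39 cases (19 and 6 adjusted over the list alone; adjusted p = 0.634 with an estimated correlation), with acs-2 at -3.35 ± 0.46 and, the other way, acdh-1 at 3.48 ± 0.3. Collagens rose in 17 and fell in 2 of 124 cases, also adjusted over the list alone (adjusted p = 0.707 with an estimated correlation), col-101 by 3.75 ± 0.44. Of 17 HIF-1 pathway genes 5 fell (5 fallen and 1 risen adjusted over the list alone), which camera did not call (adjusted p 0.244).

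In F3 the hypoxia group of WT worms had vit-1 at 11990 ± 1057 CPM against 1158 ± 404 (3.37 ± 0.49, adjusted p 0.000297). The vitellogenin genes together held 14.4 ± 0.509% of the counts against 9.975 ± 1.393% in normoxia. Here too drd-50 (3.49 ± 0.43), col-101 (3.17 ± 0.43) and T24B8.5 (4.08 ± 0.43) rose, while icl-1 (-2.57 ± 0.26), pck-2 (-1.41 ± 0.16), fat-3 (-2.53 ± 0.31) and acs-2 (-3.35 ± 0.45) fell. The small heat shock gene hsp-12.6 had no counts in hypoxia and was at least 13.1-fold lower. The hif-1 transcript fell by 0.67 ± 0.15 (adjusted p 0.0101), and hrde-1 showed 0.39 (adjusted p 0.153). Mitochondrial and ER stress genes rose in 9 of 16 cases (10 adjusted over the list alone; adjusted p = 0.0556 with an estimated correlation), with pdi-6 at 1.17 ± 0.16, dnj-7 at 1.1 ± 0.14 and the transcription factor gene xbp-1 at 0.54 ± 0.1. Lipid genes fell in 14 and rose in 5 of 39 cases (17 and 6 adjusted over the list alone), innate immune genes rose in 7 and fell in 2 of 35 (10 and 3), and both calls were lost with an estimated correlation (adjusted p = 0.634). In all 594 genes rose and 711 fell. The count was 141 without the second F3 WT normoxia library, 421 and 223 without the first and second F3 WT hypoxia libraries, 2017 with DESeq2 and 2255 in a fit of the 4 libraries alone.

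The F2 comparison depended on which version of the normoxia columns was used. As deposited, 210 genes rose and 1029 fell, and with the remainder edgeR called 0, with 318 genes at an unadjusted p under 0.05 where chance would give 777, and DESeq2 called 1. A number below that of chance means that edgeR's test with the shared spread was strict here. The 0 calls therefore do not show that nothing changed. No fit of the compared groups alone was made with the remainder. As deposited, collagens fell in 21 and rose in 3 of 124 cases (47 and 5 adjusted over the list alone, median -2.33, or -2.13 at the count floor). Cuticle and molting-cycle genes fell in 11 of 30 cases (27 adjusted over the list alone, median -3.06) and sperm genes in 8 of 25 (14, median -1.75). All 3 calls were lost with an estimated correlation (adjusted p = 0.854, 0.634 and 0.634), and with the remainder the medians were -0.35, -1.15 and -0.66. The log2 fold change of vit-1 was 1.85 ± 0.46 (adjusted p 0.0227) and 0.34 with the remainder, that of folt-2 2.03 ± 0.44 and 1.19, that of col-101 1.91 ± 0.41 and 0.58, and that of acdh-1 1.7 ± 0.28 and 1.08. The collagen gene col-49 and C23G10.11 had no counts in hypoxia and were at least 84.3-fold and 60.7-fold lower as deposited; with the remainder neither passed the test (adjusted p 1 for both). The hif-1 transcript fell by 0.79 ± 0.15 as deposited (-0.07 with the remainder), and hrde-1 showed 0.37 (adjusted p 0.162), or 0.01. Mitochondrial and ER stress genes rose in 9 of 16 cases as deposited, also adjusted over the list alone, and kept a call with an estimated correlation (adjusted p = 0.0295); with the remainder the median went from 0.5 to 0.04. Of the deposited calls 16.9% were higher, a share that DESeq2's size factors moved to 29.7%, DESeq2 itself to 32.2% and leaving out vitellogenin and ribosomal RNA genes to 29.4%. The deposited normoxia columns are averages, and their replicates correlated with r of 0.9952, against 0.9846 for those of the remainder. A fit of the 4 libraries alone rests on that narrowed spread. Without the first and second F2 WT normoxia columns in turn 229 and 171 genes were called, without the first and second F2 WT hypoxia libraries 131 and 65, and a fit of the 4 libraries alone gave 6645.

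The fit of WT pooled over F1 to F3 uses the libraries of the single generations again, so it is no separate test of them. The collagen gene col-101 rose by 2.92 ± 0.26 (adjusted p 8.75e-06; 2.59 with the remainder), vit-1 by 3.71 ± 0.64 (3.37) and folt-2 by 3.22 ± 0.56 (2.98). Lower were the lysosomal lipase gene lipl-3 (-5.25 ± 0.34; -4.6 with the remainder), the lectin gene clec-60 (-5.73 ± 0.4; -5.11), icl-1 (-2.8 ± 0.13; -1.98) and pck-2 (-1.52 ± 0.1; -1.0). All 7 passed the test with either version in the fit without a replicate block. As deposited each had the same sign in F1, F2 and F3. The F1 and F3 normoxia libraries within the F2 columns favour this, and the rule for naming the largest pooled changes required it. With the remainder the F2 log2 fold change of pck-2 was 0.08, and clec-60 had no counts in F2 normoxia. The hif-1 transcript fell by 0.78 ± 0.06 (adjusted p 2.51e-06; -0.49 with the remainder, adjusted p 0.0145), and hrde-1 rose by 0.41 ± 0.06 (adjusted p 0.000285; 0.35 with the remainder, adjusted p 0.0286). In all 3019 genes rose and 4114 fell of 14077 tested, and 1816 rose and 1636 fell with the remainder. Nearly all calls with the remainder were lost when the replicate number was added as a block, as given with the processing. Mitochondrial and ER stress genes rose in 13 of 16 cases and fell in 1 (13 and 2 adjusted over the list alone; 10 and 1 with the remainder), oocyte and eggshell genes in 19 and 1 of 23 (20 and 1; 15 risen with the remainder). Neuropeptide genes fell in 61 and rose in 3 of 92 cases (62 and 5 adjusted over the list alone; 24 fallen and 3 risen with the remainder). HIF-1 pathway genes fell in 10 and rose in 1 of 17 cases (the same adjusted over the list alone; 3 and 1 with the remainder). With an estimated correlation the first 3 calls were lost (adjusted p = 0.634, 0.634 and 0.636), and camera did not call the HIF-1 list (adjusted p 0.124).

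Genes called in P0 were compared with those of later generations, to see how far the P0 response recurred. Of the 3075 genes that rose in WT P0, 454 also rose in F1 against 178 expected for independent lists, and 271 also rose in F3 against 118 expected. Of the 3747 that fell, 861 also fell in F1 (350 expected) and 401 in F3 (172 expected). The log2 fold changes of all genes correlated with Pearson's r of 0.444 between P0 and F1 and 0.345 between P0 and F3, across genes, which are not independent replicates. With F2 as deposited 88 and 399 genes were shared (41.6 and 248 expected), a comparison that holds F1 and F3 normoxia libraries within it, and with the remainder 0 and 0, since edgeR called 0 genes there. In the mutant 21 genes rose in both P0 and F1 (23.1 expected) and 2 fell in both (8.1 expected), while 53 genes that fell in P0 rose in F1. In WT too genes were called in the opposite direction, in F1 56 of those that had risen and 40 of those that had fallen in P0, in F3 52 and 33, and in F2 as deposited 211 and 16. The correlation between mutant P0 and F1 was -0.051. For the mutant in F2 and F3 it was 0.218 and 0.247, beside 0.241 for WT F2 as deposited and 0.102 with the remainder. Of the genes that rose in mutant P0, 65.2% had the same sign in F1, 60.3% in F2 and 80.1% in F3, and of those that fell 34.3%, 71.3% and 62.9%. In WT these shares were 79.9%, 71.3% and 70.2% of the risen and 80.3%, 86.1% and 85.2% of the fallen genes as deposited, and 56.9% and 65.2% in F2 with the remainder.

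In hrde-1 worms of P0, hypoxia was followed by some of the changes seen in WT. The transport genes catp-2 (6.93 ± 0.85, adjusted p 0.000249) and nhx-6 (6.57 ± 0.87) rose, and the arginine kinase gene argk-1 and the histone gene his-45, both without counts in normoxia, were at least 72.2-fold and 102-fold higher. The yolk gene vit-1 rose by 2.49 ± 0.48 (adjusted p 0.00432), with normoxia replicates far apart (1774 ± 1779 CPM). Lower were nhr-25 (-3.83 ± 0.48), fbn-1 (-3.62 ± 0.53) and the glutathione transferase gene gst-38 (-4.97 ± 0.71). The log2 fold change was 0.4 for hrde-1 (adjusted p 0.16) and -0.03 for hif-1 (adjusted p 0.926). In all 267 genes rose and 835 fell. Without the first and second P0 hrde-1 normoxia libraries in turn 3190 and 134 genes were called, without the first and second P0 hrde-1 hypoxia libraries 80 and 1.8e+02, and a fit of the 4 libraries alone gave 0 with edgeR, where the fit of all libraries had 3744 genes at an unadjusted p under 0.05.

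Of 30 cuticle and molting genes 10 fell in these worms (14 fallen and 1 risen adjusted over the list alone; adjusted p = 0.669 with an estimated correlation). Ribosomal protein genes rose in 5 of 78 cases, or 32 adjusted over the list alone (median 0.28; adjusted p = 0.634 with an estimated correlation), with rps-13 at 0.43 ± 0.1. Histone genes, which share reads among copies, rose in 5 and fell in 2 of 49 cases (13 and 4 adjusted over the list alone; adjusted p = 0.634 with an estimated correlation), with his-11 at 2.84 ± 0.3 and the linker histone gene his-24 at -3.75 ± 0.58. Of 6 vitellogenins 3 rose (6 adjusted over the list alone; adjusted p = 0.634 with an estimated correlation). Ribosomal RNA genes held 7.24 ± 0.156% of the counts of the P0 hrde-1 hypoxia libraries and 12.5 ± 0.566% of those of F3, against 1.75 ± 0.382% and 1.79 ± 1.33% in normoxia. In F1 the share was 4.63 ± 1.99% in hypoxia and 2.82 ± 3.19% in normoxia, and in F2 6.55 ± 0.361% and 4.28 ± 1.72%. In WT groups it ran from 0.615 ± 0.601% in F1 hypoxia to 2.105 ± 1.534% in F2 hypoxia. Since poly(A) RNA was selected, the share is no measure of the ribosomal RNA in the worms.

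In F1, the mutant hypoxia group differed from normoxia in collagens, sperm genes and muscle genes. Of 124 collagens 84 rose (98 risen and 1 fallen adjusted over the list alone), with a median of 3.71, or 3.34 at the count floor, and col-3 at 4.95 ± 0.87 (300.0 ± 2.83 against 9.79 ± 4.18 CPM, adjusted p 0.00257). Major sperm proteins rose in 27 of 30 cases (29 adjusted over the list alone), msp-36 by 2.42 ± 0.38, and other sperm genes in 15 of 25 (18), with the sperm phosphatase gene gsp-4 at 2.62 ± 0.44 and the presenilin gene spe-4 at 3.07 ± 0.54. Muscle markers rose in 18 and fell in 1 of 23 cases (22 and 1 adjusted over the list alone), the myosin gene myo-3 by 1.13 ± 0.2, and cuticle and molting genes in 12 of 30 (19). These 5 calls were lost with an estimated correlation (adjusted p from 0.634 to 0.636). The same lists set apart the 2 untreated F3 hrde-1 libraries, by medians (second minus first, log2) of 3.76 for collagens, 3.92 for cuticle genes, 1.61 for sperm genes, 1.27 for major sperm proteins and 0.77 for muscle markers. Lower were the uterine lumen genes ule-2 (-2.72 ± 0.33, adjusted p 0.000802) and ule-1 (-1.79 ± 0.26) and the lysozyme gene lys-7 (-1.4 ± 0.29). The log2 fold change was -0.2 for hrde-1 (adjusted p 0.469) and 0.25 for hif-1 (adjusted p 0.291). In all 1346 genes rose and 151 fell. The count was 8 and 173 without the first and second F1 hrde-1 normoxia libraries, 605 and 817 without the first and second F1 hrde-1 hypoxia libraries, and 5020 in a fit of the 4 libraries alone.

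Later mutant generations gave few calls. In F2 edgeR called 0 genes, with 900 at an unadjusted p under 0.05, and DESeq2 called 2. In F3 edgeR called 2, with 1155 at an unadjusted p under 0.05, and DESeq2 called 14. They were test-1, for a testican-like protein, which rose by 6.51 ± 0.69 (57.4 ± 14.6 against 0.644 ± 0.641 CPM, adjusted p 8.15e-05), and the arrestin-domain gene arrd-13 (-1.19 ± 0.18, adjusted p 0.00862). Without the second F3 hrde-1 normoxia library, whose correlation of 0.903 with its replicate was the lowest of the groups, 3164 genes were called. Pooled over F1 to F3, edgeR called 1 gene of 13763, the collagen gene col-98 (0.86 ± 0.1, adjusted p 0.036), with 1530 at an unadjusted p under 0.05, and DESeq2 called 58. The average of contrasts in the fit of all libraries called many more, as given with the processing. Major sperm proteins, which share reads among copies, had no pooled call over all genes. Adjusted over the list alone 27 of 30 were called (median 1.0, camera's adjusted p = 0.634 with an estimated correlation). Among F1, F2 and F3 taken singly, only F1 had calls of these genes over all genes. The log2 fold changes of hrde-1 and hif-1 were 0.05 (adjusted p 1) and -0.18 (0.985) in F2, 0.08 (0.899) and 0.19 (0.721) in F3, and -0.04 (0.829) and 0.06 (0.796) pooled.

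Whether the strains differed in their response was tested with the interaction in each generation, as the mutant's hypoxia effect minus that of WT. In P0 54 genes had a higher and 198 a lower effect in the mutant. Fits of the compared groups alone called 0 in P0 and in F3. In F1 and in F2 as deposited they called more genes than the fit of all libraries. The difference was -4.06 ± 0.66 for vit-1 (adjusted p 0.0111), -4.61 ± 0.83 for alg-3, -3.26 ± 0.58 for col-101 and 2.31 ± 0.43 for the metallothionein gene mtl-2, and hrde-1 itself differed by -1.3 ± 0.25 (adjusted p 0.0188; hif-1 0.24, adjusted p 0.595). Major sperm proteins had a lower effect in 2 of 30 cases (22 adjusted over the list alone, median -1.84) and oocyte genes in 1 of 23 (20, median -0.97), both with adjusted p = 0.634 under an estimated correlation. The P0 count moved by over 1.5 times without each of the 8 libraries in turn, to 0 without the second P0 WT normoxia or the first P0 WT hypoxia library (edgeR; 2915 genes at an unadjusted p under 0.05 with all libraries), 2023 without the second P0 hrde-1 normoxia library and 982 with DESeq2.

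In F1 the interaction was called for 2392 genes, 1625 of them with a higher effect in the mutant. It was -6.31 ± 0.69 for vit-1 (adjusted p 9.85e-06), -6.35 ± 0.71 for folt-2, -4.74 ± 0.67 for lys-2 and 1.09 ± 0.22 for hif-1 (adjusted p 0.0038; hrde-1 -0.72, adjusted p 0.0506). Neuropeptide genes had a higher effect in 31 of 95 cases (50 higher and 1 lower adjusted over the list alone; adjusted p = 0.634 with an estimated correlation) and major sperm proteins in 25 of 30 (27; adjusted p = 0.636). The higher share of 67.9% became 55.9% with DESeq2's size factors, 56.1% with DESeq2 and 54% without vitellogenin and ribosomal RNA genes, which moved the median of all genes by -0.108. Without each library in turn the F1 count ran from 656, without the first F1 WT normoxia library, to 1823, without the second, and only the latter stayed within 1.5 times. In F3 98 genes had a higher and 48 a lower effect, a share of 67.1% that DESeq2 moved to 52.4% of 717 calls and leaving out vitellogenin and ribosomal RNA genes to 54.6%. The difference was 6.23 ± 0.84 for test-1, 4.21 ± 0.47 for the aquaporin gene aqp-1, -3.61 ± 0.57 for the small heat shock gene hsp-17 and -3.87 ± 0.56 for T24B8.5 (hif-1 0.86, adjusted p 0.0561; hrde-1 -0.31, adjusted p 0.443). Mitochondrial and ER stress genes had a lower effect in 2 of 16 cases (11 adjusted over the list alone; adjusted p = 0.0797 with an estimated correlation). The F3 count was 5217 without the second F3 hrde-1 normoxia library and 25 without the second F3 WT normoxia library.

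In F2 the interaction was called for 35 genes as deposited, 34 of them higher, and for 0 with the remainder in edgeR (1 in DESeq2). With the remainder 367 genes had an unadjusted p under 0.05 where chance would give 777, so edgeR's test was strict here too. As deposited the interaction was 4.01 ± 0.48 for aqp-1, 4.03 ± 0.59 for the alcohol dehydrogenase gene sodh-1 and 4.01 ± 0.62 for acs-2, and with the remainder 0.06, -0.2 and -0.07. For hif-1 and hrde-1 it was 0.61 (adjusted p 0.225) and -0.32 (adjusted p 0.587) as deposited, -0.11 and 0.05 with the remainder. DESeq2 moved the higher share from 97.1% to 77.6%, and without the first F2 hrde-1 normoxia library 265 genes were called. Pooled over F1 to F3, 2895 genes had a higher and 2499 a lower effect in the mutant of 14659 tested, and 1175 were called with the remainder. It was 4.65 ± 0.38 for aqp-1 (3.5 with the remainder), 5.8 ± 0.67 for lipl-3 (5.01), -3.46 ± 0.66 for vit-1 (-3.05), -2.89 ± 0.64 for folt-2 (-2.57) and 0.83 ± 0.13 for hif-1 (0.6), all 5 past the threshold both ways. For hrde-1 it was -0.47 ± 0.11 (adjusted p 0.00425), or -0.34 with the remainder (adjusted p 0.091). Oocyte and eggshell genes had a lower effect in 21 of 23 cases (21 adjusted over the list alone; 13 with the remainder) and major sperm proteins a higher one in 27 of 30 (28; 11). With an estimated correlation the adjusted p was 0.634 and 0.681.

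The WT response in P0 also differed from the mean of the F1 to F3 responses, for 3199 genes, 2008 of them with the higher effect in P0 (3109 called with the remainder). It was higher in 27 of 30 major sperm proteins (28 adjusted over the list alone), in 18 of 23 oocyte and eggshell genes (21) and in 11 of 23 glycolysis and gluconeogenesis genes (15), with adjusted p = 0.634 for all 3 under an estimated correlation. The difference was -5.38 ± 0.53 for fat-7 (adjusted p 1.11e-06), -4.78 ± 0.51 for the dehydrogenase gene dhs-20 and 1.01 ± 0.18 for pck-2, and 1.27 ± 0.2 for hrde-1 (adjusted p 0.000244; hif-1 0.5, adjusted p 0.0487, or 0.26 and 0.32 with the remainder). The count was 1189 without the second P0 WT normoxia library. In the mutant the same difference was called for 432 genes, 366 of them lower in P0 (279 called with the remainder), among them gst-38 (-4.94 ± 0.79) and, the other way, the cystathionine gamma-lyase gene cth-1 (2.94 ± 0.57). For hrde-1 and hif-1 it was 0.42 (adjusted p 0.217) and -0.12 (adjusted p 0.71). The count ran from 40, without the first P0 hrde-1 hypoxia library, to 2753, without the first P0 hrde-1 normoxia library.

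**Figure D4:**
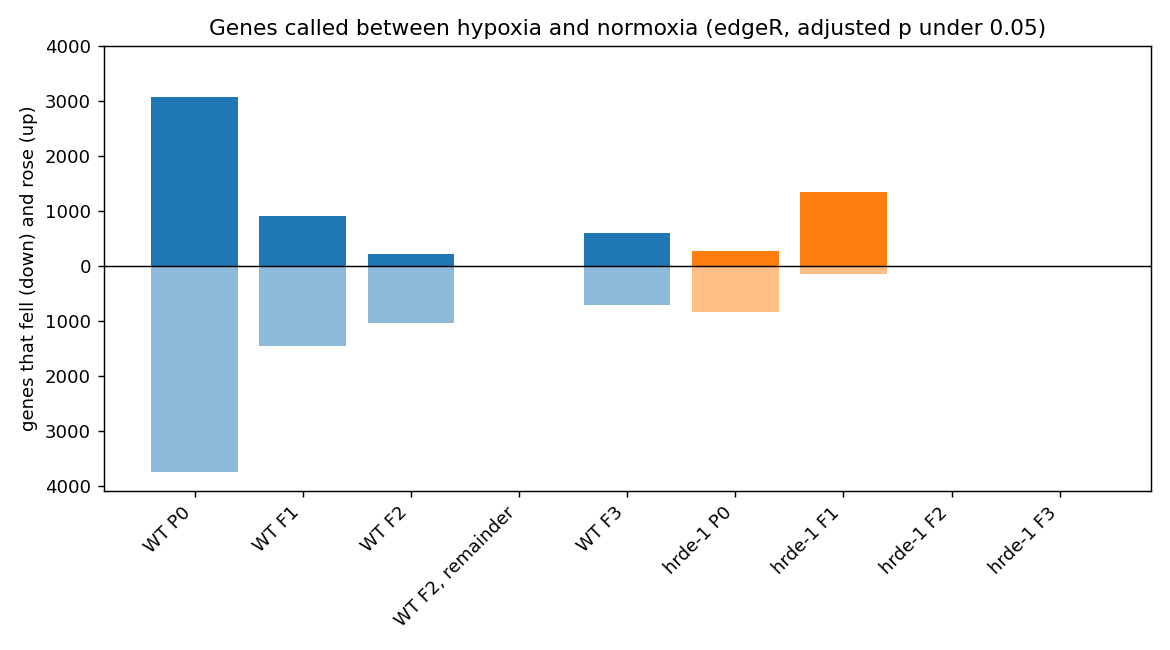
Genes that rose (up) and fell (down, paler) between hypoxia and normoxia groups at an adjusted p under 0.05 (edgeR), as bars from 0, by generation for WT and hrde-1 worms (n = 2 libraries per group). WT F2 is shown as deposited (210 risen, 1029 fallen) and with the remainder (0 called).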

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

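The tests on whether the remainder comes from hypoxia worms, on the difference between the P0 hrde-1 normoxia replicates and on the chromosome V stretch were chosen only after the values were seen. The test of DESeq2 with the remainder was written when edgeR's 0 calls with it were known, and the splits of the results with both strains on the remainder when those of the deposited columns were known.

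Differences between groups were tested directly, and each of these counts is of genes past the threshold. The hypoxia effect differed between strains for 252 genes in P0, 2392 in F1, 35 in F2, 146 in F3 and 5394 over F1 to F3. The effect in P0 differed from the mean of the later effects for 3199 genes in WT and 432 in hrde-1, and the genotype effect differed among generations for 1516. The libraries were split in 60 ways within generations, for the strain difference also within conditions, with the real split counted. The real split alone called as many genes for the strain difference over F1 to F3 (5394 calls, highest other split 382, or 1175 and 394 with the remainder). Its other splits exchanged strain labels, so strain differences present without hypoxia widened their spread. They therefore cannot decide whether the difference in the hypoxia effect is chance, and no conclusion is drawn from them. The real split also called the most genes for WT over F1 to F3 (7133, highest other 377, or 3452 and 2197 with the remainder). So it did for untreated hrde-1 against WT (5215, highest other 2906). With the remainder the untreated strains gave 2246, and 2 splits were as large, the highest other 3522, so the share stays under 5% although 1 other split called more genes than the real one. The splits of WT and of the untreated strains argue only against a chance arrangement of independent libraries. They cannot exclude chance differences between cultures, since no label says that replicates came from separate cultures. As deposited, the F2 WT normoxia columns also hold F1 and F3 libraries. For hrde-1 over F1 to F3 a chance arrangement cannot be excluded, as the real split called 1 gene and 3 splits called as many, the highest other 1518, many times the real count, which points to a structure of the samples.

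The F2 WT normoxia columns contain a further signal that no comparison uses as deposited, the remainder of 12555703 and 11633862 estimated counts. The 1239 F2 WT calls may come from the F1 and F3 normoxia libraries within the columns, since DESeq2 called 1 gene with the remainder against 2311 as deposited. Whether the remainder comes from normoxia worms at all cannot be told apart from a mislabelled hypoxia library. It correlated with F2 WT hypoxia libraries with a mean r of 0.99, above the 0.985 between its own replicates. That is near the 0.993 between the F2 WT hypoxia replicates, as was written for a mislabelled library. By replicate its mean r was 0.979 and 0.978 with F3 WT hypoxia, and 0.933 and 0.933 with F3 WT normoxia. For F1 WT it was 0.952 and 0.949 with hypoxia, and 0.935 and 0.935 with normoxia. An unchanged F2 generation, as a biological explanation, would give the same values and stays open.

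Fold changes of the hypoxia groups resembled differences between untreated replicates, which may reflect the age or stage of the worms at harvest. Of 56 correlations computed, 7 untreated replicate differences against 8 comparisons, only 4 with the F3 hrde-1 normoxia replicates were written beforehand, after a principal component plot had shown these replicates apart; the absolute r across genes was 0.659 for hrde-1 F1, 0.333 for WT F3, 0.143 for WT F1 and 0.032 for WT P0, beside 0.535 for WT F2 as deposited, 0.318 for hrde-1 F2, 0.211 for hrde-1 F3 and 0.133 for hrde-1 P0, for which nothing was written. The signs differed, with r positive for hrde-1 F1, hrde-1 F3 and WT F1 and negative for the other comparisons. The hrde-1 F3 comparison shares its normoxia libraries with this replicate difference. The WT P0 value met the bound set for excluding the explanation, but that bound rested on 1 pair and was too narrow, since WT P0 reached 0.493 with the P0 hrde-1 normoxia replicates and 0.327 with those of F3 WT normoxia. With the P0 hrde-1 normoxia replicates WT F1 reached 0.484 and WT F3 0.438, so age or stage stays open beside an effect of hypoxia in all 4 comparisons. A few abundant genes as the cause of the WT F1 calls are argued against by 2487 calls without vitellogenin and ribosomal RNA genes, beside 2350 with them.

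In hrde-1 libraries 21 neighbouring WT-expressed genes of chromosome V, from C17E7.9 at 3889161 to D1065.3 ending at 4062184, had under 0.1 CPM each, 47 counts in all against 47772 in WT over 16 libraries each. A stretch of 173024 bp missing in the hrde-1 strain could account for it, as a run of 21 was longer than the longest of 2 in 1000 shuffles of the 12739 expressed genes. Independent lowering of single genes is argued against, since 0 of the shuffles had a run as long. The 2 genes above the floor of 3 counts, C17E7.4 and C49G7.3, kept 0.0976% and 0.102% of their WT counts, beside 0.0984% for the whole run. They supply 9 and 12 of its 47 mutant counts, so that nearness is no separate support. Joint silencing of the stretch was not tested and stays open, as no DNA was measured. The stretch holds cyp-34A4, nlp-31 and phat-3, so their lower values are not shown to be an effect of hrde-1.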

How the results depend on the processing

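The remainder settings, the fit without the F2 WT normoxia columns and the library sizes without vitellogenin and ribosomal RNA genes were chosen after seeing the data. Of 500 counts under alternatives, for 37 results, 322 stayed within 1.5 times and 178 moved beyond, 99 of 208 with 1 library left out and 79 of 292 otherwise; the cause was not tested except where fewer libraries or the remainder are the setting itself. Named genes were compared 3442 times, of which 3219 kept their direction and side of the threshold, 184 lost and 27 gained a call, and 12 reversed. Of 312 list comparisons by camera's preset correlation 305 were the same, 3 lost and 2 gained a call and 2 reversed. With an estimated correlation 7 lists had a call, of which 3 were lost with DESeq2's size factors and 1 with the remainder. The reversed lists were small RNA pathway genes and meiosis and germline genes in untreated F2 mutants, with medians of -0.14 and -0.19 with the remainder.

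With DESeq2 the counts were 2311 for WT F2, 2017 for WT F3, 2 for hrde-1 F2, 14 for hrde-1 F3, 982, 1.6e+02 and 717 for the strain difference in P0, F2 and F3, 58 for hrde-1 pooled, 1080 for hrde-1 P0 minus later effects and 2588 for genotype by generation. Of the 58 calls of hrde-1 pooled 62.1% were higher. Leaving vitellogenin and ribosomal RNA genes out of library sizes moved the median log2 fold change of all genes by 0.101 in untreated F1 mutants. In fits of the compared groups alone they were 3796 for WT F1, 6645 for WT F2, 2255 for WT F3, 0 for hrde-1 P0 and F3, 5020 for hrde-1 F1, 0, 6054, 71 and 0 for the strain difference from P0 to F3, 5516 and 15 for P0 minus later effects in WT and hrde-1, 84, 194 and 35 for untreated genotype in P0, F2 and F3, 279 for genotype by generation and 2 for hrde-1 among generations. Those of these fits that use F2 WT normoxia rest on averaged columns with a narrowed spread. Without a filter the counts were 1 for hrde-1 F2, 59 for the F2 strain difference and 12 for hrde-1 pooled. The average of contrasts gave 596 for hrde-1 pooled. Without F1, F2 and F3 in turn hrde-1 pooled gave 0, 3 and 0, the pooled strain difference 1021 without F1 and 3436 without F3, and the pooled genotype 2155 without F1. Without the F2 WT normoxia columns the P0 strain difference gave 51 and hrde-1 P0 minus later effects 265.

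With the remainder the counts were 0 for WT F2 and the F2 strain difference, 3452 for WT pooled, 1175 for the pooled strain difference, 279 for hrde-1 P0 minus later effects, 2246 for pooled genotype, 3701 for genotype by generation and 8651 for WT among generations. DESeq2 with the remainder gave 1 for WT F2, 2 and 13 for hrde-1 F2 and F3, 876, 1 and 604 for the strain difference in P0, F2 and F3, 4176 for WT pooled, 58 for hrde-1 pooled, 2821 for the pooled strain difference, 905 for hrde-1 P0 minus later effects, 5103 for genotype by generation and 9080 for WT among generations. In F2 with the remainder, the remainder with the block and DESeq2 with the remainder, pck-2 in WT turned to 0.08, 0.07 and 0.09, and in the strain difference sodh-1 turned to -0.2, -0.11 and -0.23 and acs-2 to -0.07, -0.31 and -0.08. The log2 fold change of col-49 was 0 with the remainder in edgeR and DESeq2, and that of hif-1 in untreated F2 mutants 0.5 by DESeq2.

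Taken over all generations the replicate numbers did not pair the libraries. Over 24 pairs of groups within generations deviations correlated from -0.222 to 0.549, 6 above 0.1 and 3 below -0.1. The 0.549 was between F3 hrde-1 normoxia and hypoxia, so a pairing there is not excluded. With the replicate block the counts were 544 and 312 for the P0 and F3 strain differences, 0 for hrde-1 pooled and 2139 for hrde-1 among generations, and 5 of the 7 list calls with an estimated correlation were lost. With the block and the remainder they were 0 for WT F2 and the F2 strain difference, 403 and 231 for those of P0 and F3, 18 for WT pooled, 0 for hrde-1 pooled, 1677 for the pooled strain difference, 1476 for pooled genotype, 4240 for genotype by generation and 2005 for hrde-1 among generations.

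Of calls shared by P0 and a later generation, those with an absolute log2 fold change of at least 1 were 155, 30 and 97 higher in WT F1, F2 and F3 and 13 in hrde-1 F1. With the remainder 0 higher and 0 lower calls of WT P0 and F2 were shared. Each library left out in turn gave 3717 to 5811 calls for WT P0, 873 to 1723 for F1, 65 to 229 for F2 and 141 to 1198 for F3, and for hrde-1 80 to 3190, 8 to 817, 0 to 2 and 1 to 3164. The strain difference ran from 0 to 2023 in P0, 656 to 1823 in F1, 15 to 265 in F2 and 25 to 5217 in F3. Pooled over F1 to F3 the ranges were 6111 to 7381 for WT, 0 to 21 for hrde-1 and 4181 to 7130 for their difference. P0 minus later effects ran from 1189 to 3152 in WT and 40 to 2753 in hrde-1. Untreated genotype ran from 1291 to 5592 in P0, 2682 to 4531 in F1, 349 to 859 in F2, 588 to 3554 in F3 and 4183 to 6081 pooled, genotype by generation from 720 to 3688, and generations from 2425 to 5560 in WT and 2825 to 7883 in hrde-1. Depth limits genes near the floor of 3 counts.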

Other observations

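Untreated mutants also differed from WT in lists of germline, histone and cuticle genes, in part described above for P0 and F1. No call of these lists over P0 to F3 held with an estimated correlation. Vitellogenin genes, for yolk proteins, rose in 5 of 6 cases over P0 to F3, also adjusted over the list alone (4 with the remainder). Among them vit-1 stood at 8356 ± 4566 CPM against 1238 ± 1531 (SD, n = 8 columns each, those of F2 WT holding F1 and F3 libraries again). Its log2 fold change was 3.93 ± 0.68 (adjusted p 0.000785 in edgeR), or 3.7 with the remainder. The vitellogenin genes together differed less. In untreated mutants they held 8.31%, 16.28%, 15.045% and 14.045% of the counts from P0 to F3. In untreated WT worms they held 6.235%, 8.525%, 10.795% as deposited and 9.975%. Oocyte and eggshell genes rose in 19 of 23 cases (20 adjusted over the list alone; 6 with the remainder), and meiosis and germline genes in 13 of 27, also adjusted over the list alone (5 with the remainder), among them the P-granule helicase gene glh-1 (0.83 ± 0.12, adjusted p 0.000197; 0.73 with the remainder). By generation oocyte and eggshell genes rose in 21 cases in P0 and 16 in F1, also adjusted over the list alone, and in 0 in F2 and F3 by edgeR (1 and 4 at an unadjusted p under 0.05; DESeq2 0 and 3), with medians of 1.08, 0.74, 0.17 and 0.26. Meiosis and germline genes rose in 18 cases in P0 (19 adjusted over the list alone), 11 in F1 with 1 fallen (the same), 0 in F2 by edgeR (1 at an unadjusted p under 0.05; DESeq2 1) and 1 in F3. None of these calls in single generations held with an estimated correlation (lowest adjusted p 0.634). The WT normoxia libraries of P0 stand apart, and without P0 11 oocyte and 8 germline genes rose in the pooled fit, without F1 5 and 3. Histone genes, which share reads among copies, rose in 11 and fell in 2 of 49 cases, the same adjusted over the list alone (10 and 0 with the remainder). Cuticle and molting genes fell in 11 and rose in 1 of 30 cases, the same adjusted over the list alone (4 and 1 with the remainder), with the collagen gene dpy-17 at -3.23 ± 0.54 (adjusted p 0.000659; -2.74 with the remainder). Without F1 5 cuticle and molting genes fell and 1 rose, and their median went from -0.51 to 0.05. Camera called all 5 lists over P0 to F3, and with an estimated correlation the calls were lost (adjusted p = 0.634, 0.677, 0.712, 0.669 and 0.745).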
